A study of Arabidopsis thaliana with 2 samples.

How the data were processed

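Leaves of 2-week-old Arabidopsis plants were sampled after 24 h at 4 °C. Per the labels' protocols, plants grew in long days at a photon flux of 90 µmol per square metre per second, which was lowered to 40 during the cold, and total RNA went into Illumina libraries. There was 1 library of Col-0 and 1 library of npr1-1, grouped by the genotype label.

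The deposited values are CPM (read counts scaled to a fixed total over the listed genes), per the file headers, written with a decimal comma. Each library's values sum to 1000000 over 18345 genes of type mRNA. TopHat2, an aligner, DESeq2 and the build TAIR10 are named in the submitters' processing notes without version or role. The read counter, its use of strand, the filter that chose the listed genes and any pooling of plants are not given in the sources used here. The authors' CPM values were used as deposited. Each was a whole multiple of what 1 read is worth in its library, and dividing by that step gave whole numbers within 0.01 for 100% of values. The recovered reads numbered 50864103 for Col-0 and 50976521 for npr1-1. They were used for counting intervals and added alternatives. PCR copies are not separate molecules, so the intervals cover counting error only.

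Gene IDs were matched to the reference gene table of the assembly TAIR10.1, and 18154 of 18345 matched. Coordinates are those of the deposited table. Of the gene models 1237 pairs overlap, 1101 of them on opposite strands, and 50 pairs have the same position and the same reads, so such genes cannot be separated. Near-identical copies were sought by aligning transcripts to all annotated transcripts with BLAST+ 2.17.0, at 95% identity over at least 50% of the length, and in a wider search at 90% identity.

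The difference per gene was log2(CPM + 1) in npr1-1 minus Col-0, over genes with at least 5 CPM in at least one library, and 2-fold was a difference of 1 on that scale. The plan had foreseen trimmed-mean scaling for counts and this route for normalized values, which was followed. With 1 library per genotype no test across genes was run. Ratios of single genes carry an exact conditional binomial (Clopper-Pearson) 95% interval from the recovered reads. For each gene list the median difference was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression, as a description of these libraries. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. In simulated libraries of 18345 genes for npr1-1 against Col-0, 200 genes well above the minimum were changed 3-fold. The procedure recovered 100% of the changed genes in the right direction, called 0 unchanged genes, and 95.2% of the counting intervals held the true ratio. In 100 simulated pairs that differed by counting error alone, 0 genes were at least 2-fold apart in either direction. Both simulations held counting error only and no spread between plants. The mean SD of the log2 difference in the 100 pairs was 0.064, against 0.290 in the data. The simulations therefore give no rate of false calls for these libraries.

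Gene lists, the settings and the rule for named genes were fixed before the data were examined. Named genes are NPR1, the 12 genes with the largest difference in each direction, the 4 members with the largest difference of each list, all HSFA1 and clock genes, and CBF1, CBF2, CBF3, COR15A, RD29A, KIN1, PR1 and PR2. Genes named outside this rule (FKBP62, HSFB1, DREB2A, GOLS1, HSP101, SAG13, CHS, HEI10, KIN2, BIP2, BGLU23, STM, COR28, PDF1.2A, JAZ10, ATMG00030, AT1G07887, AT1G32630, AT2G04070, AT3G06365 and, in the closing, AGO2, NAC103, AOX1A, AT1G63980, SPO11-2 and TOM7-2) were chosen after their values were seen or are partners and markers. A list member was left out where the reference gave it another name. Alternatives were other scalings, filters, pseudocounts, fold thresholds and summaries of a list. Added after the data were seen were trimmed-mean scaling, the route of 20 reads without a pseudocount, lists without the name rule, list medians over nuclear totals, a correction for transcript length and counting models at one position once. A count test on the recovered reads was not run, since 1 library per genotype leaves no spread to test against.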

Results

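RNA sequencing was used to measure transcript levels in leaves of 2-week-old Arabidopsis thaliana plants that had been kept at 4 °C for 24 h. Wild-type plants of the accession Col-0 were set against the mutant npr1-1, which carries a point mutation in NPR1, a co-activator of transcription needed for responses to salicylic acid. Each genotype was represented by 1 library. The deposited table listed 18345 genes in both, and the reads recovered from its values came to 50864103 for Col-0 and 50976521 for npr1-1. At this depth a level of 5 CPM (read counts scaled to a total of 1000000 per library) stood for 254 reads in Col-0 and 255 reads in npr1-1. No library from plants kept warm was analysed here, so the comparison was between genotypes in the cold and gave no measure of the cold response itself. Because there were no replicates, the differences had no replicate check, no p-value was computed across genes, and every interval given here covers counting error only.

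The first value examined was that of the targeted gene. NPR1 (AT1G64280, chromosome 1, 23852748 to 23855566, minus strand, TAIR10) stood at 22.02 CPM in the Col-0 library and 18.7 CPM in the npr1-1 library, or 1120 and 954 reads. The npr1-1 to Col-0 ratio was 0.850, with a 95% counting interval from 0.779 to 0.927. A point mutation need not lower the transcript, so this level does not check the genotype.

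The comparison of npr1-1 with Col-0 asked which transcripts of cold-treated leaves differ when NPR1 is mutated. The libraries were alike for most genes, while 6 gene lists, for heat shock, abscisic acid, touch, jasmonate and ethylene, endoplasmic reticulum folding and salicylic acid, had median log2 differences (npr1-1 minus Col-0) from -0.80 to -0.41, and those for flavonoids and glucosinolates had 0.47 and 0.33. Among the 13976 genes with at least 5 CPM in at least one library, 102 genes were at least 2-fold apart on the log2(CPM + 1) scale, 28 of them higher and 74 lower in npr1-1. The log2 differences of these 13976 genes had a median of -0.05, and 97.0% of the genes were within 1.5-fold. The number depends on the pseudocount and on the minimum. With a pseudocount of 5 CPM it was 61 and with 0.1 CPM it was 129, and with a minimum of 1 CPM it was 153. With a minimum of 20 reads and no pseudocount, which changes both choices, it was 393.

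**Figure D1:**
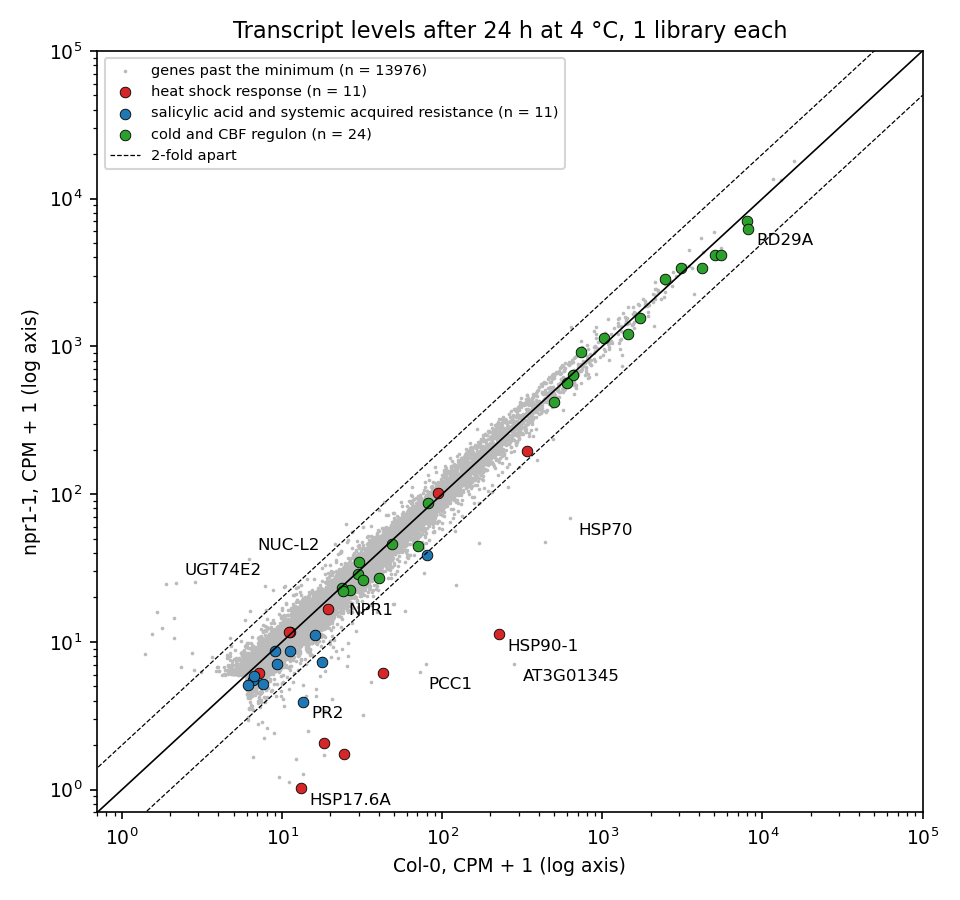
Transcript level of each gene past the minimum in the Col-0 library (x axis) and the npr1-1 library (y axis), as CPM + 1 on log axes, with members of 3 gene lists in colour, equality as a solid line and 2-fold differences as dashed lines. Most of the 13976 genes lie near the solid line, and HSP90-1, HSP70 and HSP17.6A lie far below it.

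Among the 12 lowest genes were several chaperone genes. HSP90-1 (AT5G52640), a cytosolic HSP90 induced by heat, stood at 224 CPM in Col-0 and 10.3 CPM in npr1-1, a 21.7-fold lower level with a counting interval from 19.9 to 23.7. HSP70 (AT3G12580, chromosome 3, 3991261 to 3993792) stood at 624 and 67.6 CPM, and was 9.23-fold lower. The small heat shock protein genes HSP17.6II and HSP17.6A are neighbours on chromosome 5. HSP17.6II had 1196 reads in Col-0 and 38 reads in npr1-1, and HSP17.6A had 618 reads and 1 read. For HSP17.6A the ratio of Col-0 to npr1-1 was 619, with an interval from 111 to 24503. AT1G07400, annotated as an HSP20-like chaperone, stood at 17.1 and 0.73 CPM, and AT3G55920, a cyclophilin-like peptidyl-prolyl isomerase, at 12.4 and 0.27 CPM.

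The heat shock response list held 25 genes that were in the table, of which 11 had a matching name in the reference and passed the minimum. Of these 11 members 5 were at least 2-fold lower in npr1-1, 6 lay between and 0 were at least 2-fold higher. The 5 were HSP90-1, HSP17.6II, HSP17.6A, FKBP65 and HSP101, the last being a disaggregase at 41.6 CPM in Col-0 and 5.16 CPM in npr1-1. FKBP65 stood at 17.3 and 1.08 CPM. Of the others FKBP62, the median member, stood at 338 and 194 CPM. The others also included the transcription factor genes HSFB1, at 10.2 and 10.6 CPM, and DREB2A, at 18.4 and 15.67 CPM, as well as the galactinol synthase gene GOLS1, at 92.5 and 101 CPM. The median log2 difference of the list was -0.80, below all 10000 random lists of the same size matched on expression. With members included regardless of the minimum it was -0.47, and with all listed gene IDs, whatever their name in the reference, it was -1.80. As the mean of the members it was -1.70.

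The HSFA1 factors, the main activators of the heat shock response and named in the title of the series, were at similar levels in both libraries. HSFA1A stood at 5.27 CPM in Col-0 and 5.28 CPM in npr1-1, HSFA1B at 8.81 and 7.85 CPM, HSFA1D at 5.80 and 5.32 CPM, and HSFA1E at 10.99 and 9.65 CPM. The counting interval of the ratio included 1 for HSFA1A, HSFA1B and HSFA1D, and reached 0.993 for HSFA1E. The median of the 4 genes was -0.13, at percentile 30.4 of matched random lists. The 7 TGA factors, bZIP partners of NPR1 at defence promoters, had a median of -0.14, at percentile 16.5. Among them TGA3 stood at 42.3 and 33.3 CPM and TGA2 at 7.88 and 9.44 CPM.

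Genes of salicylic acid signalling and systemic acquired resistance were lower in the npr1-1 library. All 11 list members past the minimum had negative log2 differences, 3 of them at least 2-fold, and the median was -0.41, below all 10000 matched random lists. PR2, a beta-1,3-glucanase gene, had 640 reads in Col-0 and 150 reads in npr1-1, a 4.28-fold lower level with an interval from 3.57 to 5.14. PR5 stood at 79.5 and 37.8 CPM and DMR6, a salicylic acid hydroxylase gene, at 16.7 and 6.30 CPM. WRKY70 differed less, at 6.63 and 4.198 CPM. PR1, the usual marker of this pathway, was below the minimum in both libraries, with 157 reads in Col-0 and 1 read in npr1-1. Its Col-0 to npr1-1 ratio was 157, with an interval from 27.8 to 6254. PCC1 (AT3G22231), a gene named for its control by pathogens and the circadian clock, stood at 72.0 and 5.24 CPM. Its neighbour AT3G22235, at 78.6 and 6.02 CPM, shares near-identical sequence with PCC1, so the split of reads between them is uncertain.

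Genes of the CBF cold regulon were close in both libraries, and none of the 24 members past the minimum was 2-fold apart. The median log2 difference was -0.14, with 18 members below 0 and 6 above, and this small shift lay at percentile 0.5 of matched random lists. The transcripts of this list were short, with a median of 908 bases against 1614 for all genes past the minimum. Short transcripts were higher in npr1-1 in general, so that trend runs opposite to the shift. The CBF genes encode the transcription factors that switch on this regulon. CBF1, below the minimum, stood at 3.58 and 3.45 CPM, CBF2 at 28.6 and 28.0 CPM, and CBF3 at 39.5 and 25.9 CPM. The difference of CBF2 changed sign, to 0.01, under median-ratio scaling. COR15A stood at 7992 and 7042 CPM, RD29A at 8117 and 6243 CPM, and KIN1 at 734 and 916 CPM. KIN1 has a near copy, KIN2, at 90% identity or more, which leaves the split of reads between them uncertain. The lowest of the 24 members was COR27, with a log2 difference of -0.67, and BAM3 (AT4G17090), a chloroplast beta-amylase gene whose model overlaps a neighbouring gene, had -0.41. COR28, left out because the reference gave it another name, had -0.76.

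**Figure D2:**
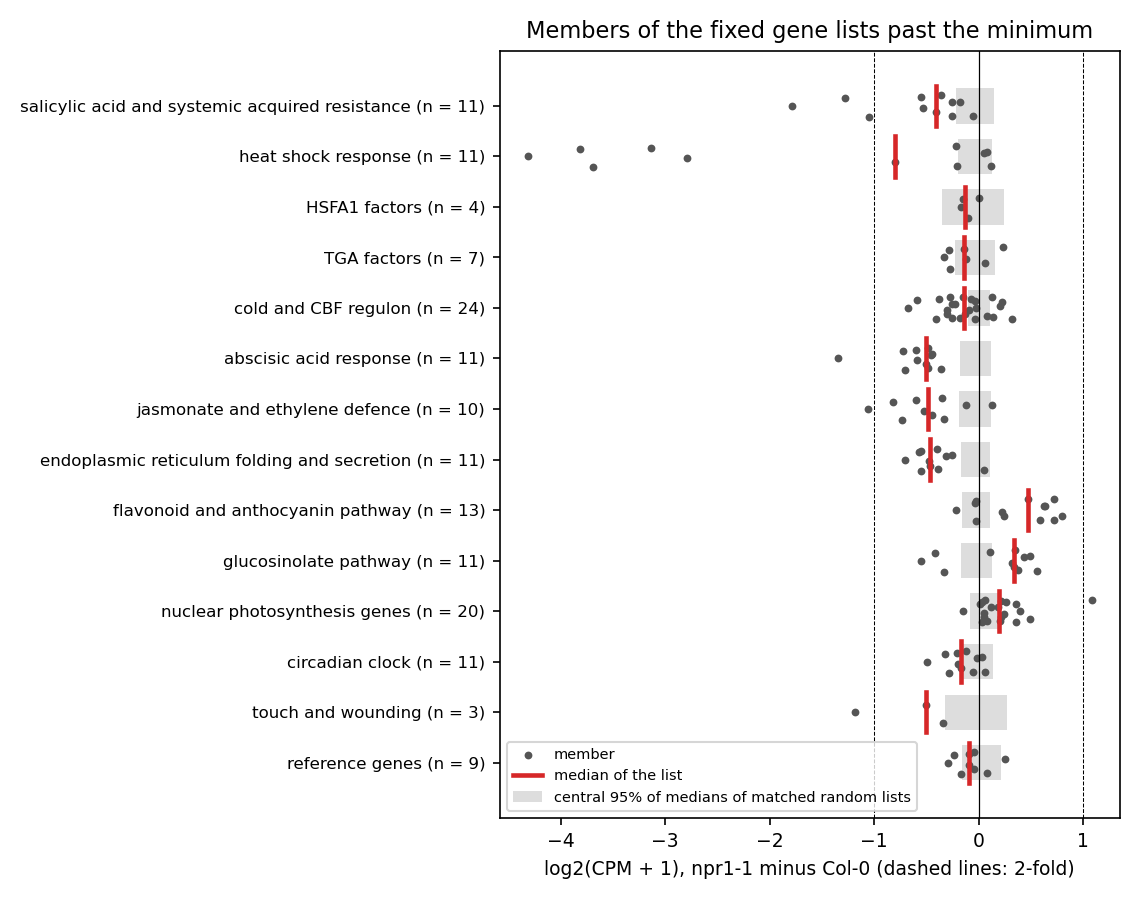
Log2(CPM + 1) in npr1-1 minus Col-0 for each member of the fixed gene lists past the minimum (points), the median of each list (red bars) and the central 95% of medians of 10000 matched random lists (grey boxes), with 2-fold differences as dashed lines. The heat shock list spreads from -4.31 to 0.12, while the 24 cold and CBF members lie between -0.67 and 0.32.

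Lists for other stress pathways were also lower in npr1-1, with medians nearer to 0 than that of the heat shock list at the 5 CPM minimum. This order depends on the minimum. Without it the heat shock median was -0.47, no longer below the abscisic acid median of -0.51, whose list lost no member to the minimum. All 11 genes of the abscisic acid response were lower, with a median of -0.51, and HAI1, a protein phosphatase gene, was the only one 2-fold lower, at 19.1 and 6.91 CPM. RD29B had -0.72, ABI2 -0.71 and NCED3 -0.60. Of 10 jasmonate and ethylene genes past the minimum 9 were lower, with a median of -0.48. Below the minimum, PDF1.2A had 192 reads in Col-0 and 18 reads in npr1-1, whereas JAZ10 had 96 and 94 reads. LOX2, a lipoxygenase of jasmonate synthesis, stood at 489 and 234 CPM, while JAZ1 had -0.82, AOC1 -0.74 and MYC2 -0.60. A reference transcript of AT1G32630 on the opposite strand covers MYC2, although their deposited models do not overlap, so its read assignment is uncertain. The endoplasmic reticulum folding genes had a median of -0.47, with 10 of 11 lower. CRT3 had -0.70, BZIP60 -0.57, CNX1 -0.55 and BIP1 -0.55, the last with uncertain read assignment because BIP2 is near-identical. The medians of these 3 lists lay below all 10000 matched random lists. The 3 touch genes had a median of -0.51, at percentile 0.2, with TCH3 at 19.9 and 8.22 CPM, TCH2 at -0.51 and TCH4 at -0.35.

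Pigment, glucosinolate and photosynthesis genes were modestly higher in npr1-1. The flavonoid and anthocyanin list had a median of 0.47, above all 10000 matched random lists, with 9 of 13 members higher and 0 at least 2-fold. The late anthocyanin genes led it, with UF3GT at 21.8 and 38.7 CPM, LDOX at 80.7 and 133 CPM, 5MAT at 20.7 and 34.8 CPM and GSTF12 at 76.8 and 120 CPM. CHS, the entry enzyme of the pathway, stood at 1906 and 1873 CPM. The glucosinolate list had a median of 0.33, at percentile 99.98, with members going both ways. MYB29, MAM3 and CYP83A1 of the aliphatic branch had 0.55, 0.49 and 0.43, whereas CYP79B2 of the indolic branch had -0.55. Of 20 nuclear photosynthesis genes 19 were higher, with a median of 0.19 at percentile 98.2, which became percentile 96.7 without RBCS2B. The median transcript length of this list was 1108 bases, against 1614 for all genes past the minimum. Short transcripts were higher in npr1-1 in general, and the median of 0.19 is not corrected for this trend. RBCS2B stood at 637 and 1348 CPM, RBCS1B had 0.49, RCA 0.40 and LHCB3 0.36. Members of the RBCS family resemble one another closely, so the split of reads among them is uncertain.

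Of the 28 genes at least 2-fold higher in npr1-1, RBCS2B was the only one on a fixed list. AT2G04050, annotated as a MATE efflux family protein, had 45 reads in Col-0 and 1208 reads in npr1-1, a ratio of 26.8 with an interval from 19.9 to 36.9. It has a copy, AT2G04070, at 90% identity or more, which makes its read assignment uncertain. UGT74E2, a glycosyltransferase of indole-3-butyric acid, had a ratio of 20.4, from 15.73 to 26.9. NAC044 had 33 and 758 reads, and GMI1, a gene induced by gamma irradiation and mitomycin C, had 95 and 1251 reads. NUC-L2, a nucleolin gene, stood at 5.21 and 35.5 CPM, QQS at 1.12 and 13.4 CPM, and NDB4, a NAD(P)H dehydrogenase gene, at 0.39 and 7.24 CPM. The other genes among the 12 highest were AT2G18193, AT5G60250, AT5G58610, AT3G58270 and AT5G13210, with log2 differences of 2.87, 2.80, 2.33, 1.62 and 1.61.

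Several of the 12 lowest genes were of unknown function or uncertain assignment. AT3G01345 (chromosome 3, 129138 to 130749) stood at 281 CPM in Col-0 and 6.02 CPM in npr1-1, the largest log2 difference of all genes past the minimum at -5.33. AT5G15360 had 512 and 6 reads. MRD1 (AT1G53480) stood at 31.0 and 2.197 CPM, but its model overlaps HEI10 on the opposite strand, and strand use in the counting was not given in the sources used here. The MRD1 transcript is also near-identical to AT1G07887 over 91.0% of its length, so its read assignment is uncertain. AT2G01021 (chromosome 2, 6571 to 6672) stood at 439 and 46.6 CPM. It is annotated beside ribosomal RNA genes, and its transcript is identical to that of AT3G06365 over its whole length, so its reads cannot be placed.

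**Figure D3:**
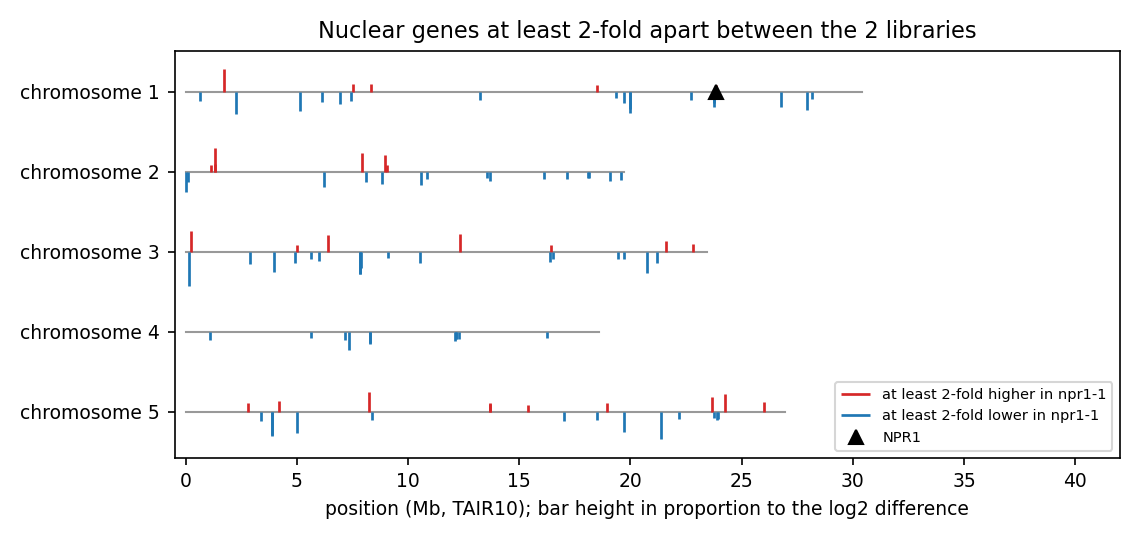
Positions on chromosomes 1 to 5 (x axis, Mb, TAIR10) of nuclear genes at least 2-fold higher (bars up, red) or lower (bars down, blue) in npr1-1, with bar height in proportion to the log2 difference and NPR1 as a triangle. The genes are spread over all 5 chromosomes.

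Clock, reference and tissue marker genes were examined for differences in harvest or tissue. The 11 circadian clock genes had a median of -0.17, at percentile 1.7, which became percentile 3.15 without LUX and 3.02 after subtracting the median of each gene's length bin. The morning genes CCA1 and LHY had -0.02 and 0.06, RVE8 -0.17, PRR9 -0.06 and PRR7 -0.28. The evening genes TOC1, PRR5, GI, ELF3 and ELF4 had -0.20, -0.13, -0.21, 0.03 and -0.32, and LUX had -0.49. CCA1 turned to 0.02 under median-ratio scaling. The reference genes had a median of -0.09, at percentile 12, with PP2AA3 at -0.30, UBC9 at -0.23, ACT8 at -0.17 and GAPC2 at 0.25. Of 4 root markers only BGLU23 was in the table, at 47.2 and 48.8 CPM. STM of the shoot meristem stood at 2.54 and 2.69 CPM. None of the 7 seed markers and none of the 7 flower and inflorescence markers was in the table. Of the senescence list only NYE1 passed the minimum, at 20.8 and 21.1 CPM, and the list's median became negative with members below it, at -0.41 with a minimum of 100 reads and -0.27 without a filter. SAG13 had 109 and 38 reads. Transcripts of 88 plastid genes summed to 5162 CPM in Col-0 and 4654 CPM in npr1-1, although only 31 of the 88 were lower in npr1-1. Those of 18 mitochondrial genes summed to 60.3 and 23.501 CPM, a ratio of 0.390 with an interval from 0.364 to 0.417, and 17 of the 18 were lower in npr1-1. A single gene, ATMG00030, made up 24.5 and 5.83 CPM of these mitochondrial sums.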

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

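The scalings moved little: median-ratio and trimmed-mean (TMM) scaling shifted the median of all genes by less than 0.1 and gave 97 genes at least 2-fold apart, against 102. Thresholds moved the number more. Without a filter and with 0.5 added to each count 462 genes were apart, 147 higher and 315 lower. A fold of 4 left 31, 10 higher and 21 lower, and a fold of 1.5 gave 415, 127 higher and 288 lower. A pseudocount of 5 gave 61, 14 higher and 47 lower, and one of 0.1 gave 129, 30 higher and 99 lower. With a value minimum of 1 or none, 153 were apart, 46 higher and 107 lower. With 20 reads and no pseudocount, an alternative added after the data were seen, 393 were apart, 114 higher and 279 lower. Besides the fold thresholds, these settings differ by construction in which low genes enter, in the pseudocount that shrinks them, or in both.

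The heat shock median of -0.80 became -0.76 under both median-ratio and trimmed-mean scaling, -0.73 at 100 reads, -0.47 without a filter, -0.51 without its largest member, -1.70 as a mean, -1.80 with all listed gene IDs and -0.74 after the length correction. The salicylic acid median became -0.61 as a mean, and the cold regulon median -0.10 under both scalings. Beyond the settings that add or drop members, the cause was not tested. Of 183 list values under other settings 37 moved by more than the counting interval, taken here from 1000 Poisson resamples of the list median. Of the 183, 2 had the other sign, both for senescence (-0.41 at 100 reads and -0.27 without a filter). Of 356 values of named genes 86 moved by more than that interval, and 4 had the other sign, for CBF2 and CCA1. Alternatives named for replicate libraries were not run. Counting error limits genes near 5 CPM little, but the spread between plants was not measured.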

Other observations

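The tests here of scaling, of transcript length, of harvest, of neighbouring pairs and of the NPR1 region, as well as all gene families, were chosen only after results had been seen. Families were taken from product names in the reference annotation. Cytosolic ribosomal protein genes moved together: 206 of 227 were higher in npr1-1, with a median log2 difference of 0.33, above all 10000 matched random lists. Short transcripts were higher in npr1-1 in general, with a median of 0.11 in the shortest and -0.11 in the longest of 20 length bins, and ribosomal protein transcripts are short. After subtracting the median of the length bin the family's median was 0.28. Xyloglucan endotransglucosylases, which remodel cell walls, had a median of 0.22 at percentile 99.97.

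The medians of several families lay below the central 95% of random lists. Those random lists were matched on expression and not on transcript length, and the values given here are not corrected for the length trend. TIR-NBS-LRR disease resistance genes were lower in 39 of 44 cases, with a median of -0.17 at percentile 0.07, cysteine-rich receptor-like kinases had -0.32 at percentile 0.02, and glutathione S-transferases -0.17 at percentile 0.18. The Hsp70 family had -0.43, below all matched random lists, with 12 of 14 genes lower, and NAC factors had -0.16 at percentile 1.98. The medians of the other 11 families lay within the central 95% of random lists. They were DnaJ co-chaperones (-0.10), HSP20-like proteins (-0.06), cytochrome P450 enzymes (-0.04), UDP-glycosyltransferases (-0.08), WRKY factors (-0.13), 3 genes with a protein phosphatase 2C product name (-0.11), histones (0.03), expansins (0.07), peroxidases (0.08), late embryogenesis abundant proteins (-0.12) and thioredoxins (-0.08). The HSP20-like family, chosen by product name, did not hold the small heat shock genes HSP17.6II and HSP17.6A, at -3.81 and -3.69.

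The lower heat shock transcripts were weighed first. The median-ratio and trimmed-mean factors of npr1-1 over Col-0 were both 0.971, and the ratio of nuclear totals was 1.001. These near-equal factors argue against depth as the cause. The list's median stayed at -0.76 or lower under these 3 scalings, but factors so near to 1 could move it little. A trend with transcript length ran through the genes past the minimum (Spearman rho -0.19), but the list's median was -0.74 after subtracting the median of each length bin, which argues against the trend as the whole cause. Reads shared with near-identical copies are argued against too, since 0 of the 5 members at least 2-fold lower had such a copy. A difference between harvests other than genotype cannot be told apart from the mutation, because each genotype had 1 library. The length trend, the mitochondrial transcripts (a ratio of 0.390, with 17 of 18 genes lower in npr1-1) and AT2G01021 beside ribosomal RNA genes (9.43-fold lower) also set these libraries apart, and whether they share a source with the heat shock difference was not tested. An effect of the npr1-1 mutation on these genes also stays open as a hypothesis, and was not tested.

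Neighbouring genes differed together in 8 pairs, where 10000 random placements gave a median of 0 and a highest value of 5, which argues against chance placement. Of the 8 pairs 6 do not overlap, among them HSP17.6II with HSP17.6A, so double counting of reads over overlapping models does not account for them. Among the 6, the pair PCC1 with AT3G22235 is near-identical in sequence, and reads shared between near-identical neighbours cannot be told apart from a joint difference for this 1 pair. The 5 pairs with neither overlap nor near-identical sequence lie above the central 95% of random placements, which reached 2, but only equal the highest value. For the 2 overlapping pairs, MRD1 with HEI10 and AT1G63980 with SPO11-2, shared reads cannot be told apart from a joint difference, since strand use is not given. A segment linked to NPR1 and carried along in the mutant line is argued against for 6 of the 8 pairs, which lie on other chromosomes. For the other 2, which are the overlapping pairs and lie within 5 Mb of NPR1, it stays open: 0.876% of genes within 5 Mb of NPR1 were at least 2-fold apart, against a median of 0.811% in other windows and a highest value of 1.62%. Windows this wide cannot exclude a shorter segment. AT1G63980 and SPO11-2 lie at 23740516 to 23745374, close to NPR1, which starts at 23852748. TOM7-2, at 23833088 to 23833321, is closer still and was at least 2-fold higher in npr1-1, with 134 reads in Col-0 and 351 reads in npr1-1.

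The genes highest in npr1-1 included several known from DNA damage (NAC044, GMI1) and from mitochondrial stress (UGT74E2, NDB4, AT2G04050), which prompted 2 hypotheses. Counting error is argued against, since 0 genes were 2-fold higher in 100 simulated pairs. Of 12 DNA damage genes whose values had not been looked at, 8 passed the minimum. Their median was 0.23 at percentile 99.78, which goes with a mild DNA damage response. However, 2 of the 8 were lower, among them AGO2 at -0.70, and none of the 8 was 2-fold higher. NAC103, left out by the minimum, had 53 reads in Col-0 and 221 reads in npr1-1. Mitochondrial stress genes not looked at before had a median of -0.16 at percentile 6.81, and AOX1A stood at 92.9 and 116 CPM. That test leaves out the 6 members at least 2-fold higher, so it does not exclude a response of part of the list, and the question stays open.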
